A study of Mus musculus with 9 samples.

How the data were processed

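Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was compared across 9 libraries of mouse cells on the way from epiblast-like cells to primordial germ cell-like cells. There were 6 immunoprecipitated libraries and 3 inputs, each the only library of its group. Per the labels' protocols, embryonic stem cells were turned into epiblast-like cells and then grown as floating aggregates with leukaemia inhibitory factor, with or without BMP4 and WNT3A. Chromatin was fixed with formaldehyde, sonicated and immunoprecipitated, and DNA was sequenced as single-end reads of 50 bp on a SOLiD 5500xl instrument, per the labels' protocols. BV is a Blimp1-mVenus reporter line and PV a Prdm14-mVenus reporter line, per the labels. The labels give 12, 24 or 36 h for the SMAD1 libraries, and the titles name no time for the T and TCF1 libraries. They also do not say which library received which cytokine, and that is not used here.

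The deposited values are whole-number read counts in windows of 2 kb that step by 1 kb along the genome, with no normalization, as the values show. Bowtie 0.12.8 and the genome build mm9 are named in the submitters' processing notes, and every coordinate given here is an mm9 window coordinate as the deposited count tables write it. Filters on duplicate or multiply placed reads are not given in the sources used here. Because windows overlap, each read is counted in 2 windows, and depth was taken from every other window. In 8 of the libraries the windows split into 1 kb bins with at most 0.291% of bins below 0, whereas in the input titled BVSC 47.4% of bins came out below 0, so its counts were made by another rule and its 1 kb bins were not used.

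Each library was scaled to a mean of 1 over 1977886 autosomal windows of typical input level, those between the 10th and 90th percentile of the mean of the 3 inputs. Windows on the autosomes and the X chromosome were used where the mean scaled input was at least 0.25 and no input exceeded 3. This left 2363215 of 2639004 windows (89.5%), with 274608 windows lost for low input and 1181 for high input in at least 1 input. Enrichment was the scaled immunoprecipitated value over the scaled input, with a pseudocount of 0.5 on both. A window was called at an enrichment of at least 4 and a scaled immunoprecipitated value of at least 4, and overlapping or adjoining called windows were merged into a region. The input of the same line served as background, input BV for BV libraries and input PV for PV libraries. Plain ratios without a pseudocount are given with exact (Clopper-Pearson) 95% intervals on the split of the 2 counts. Intervals and limits of a count of 0 cover counting error only, since reads made by PCR are not independent molecules, and with 1 library per group there is no spread between replicates and no p-value across libraries.

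The filter keeps every input below the level that a call needs, so the same rule on one input against another could call nothing in these windows. The background was therefore counted in windows filtered by the inputs other than the one tested, at full depth and thinned to the depth of each immunoprecipitated library, an alternative chosen after seeing the data. Overlap meant sharing 1 bp or more, and each overlap was set beside 100 random relocations of the smaller set within the windows kept and beside 5 pairs of simulated libraries with no enrichment, which share an input wherever the real pair does. No region was called in the simulated pairs, so they say nothing about what a shared input adds to an overlap. The level of 1 library at the regions of another was summarised as a median and compared with 10000 random sets of windows of the same number matched on mean input. For the SMAD1 time course, all regions called at 12, 24 or 36 h in BV were merged, and each was measured at the window with the highest mean log2 enrichment over these libraries. Intervals of medians come from the binomial ranks of the regions, which are not replicates of the experiment.

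The calling rule was tested on simulated data for each library, with 40 regions planted per fold size. They were planted only in autosomal windows with a mean input near the typical level, and all 2363215 windows were searched. The rule called no region that was not planted. The setting largely fixed this result, since the counts held only counting error around the mean of the inputs, which the filter keeps below the level of a call. It therefore says nothing about false calls from antibody background or from reads made by PCR. Of the planted regions, none was found at 3-fold, and between 35 and 57.5% were found at 5-fold, depending on the library. Between 87.5 and 100% were found at 6-fold, and all at 8-fold. Regions of lower enrichment are therefore undercounted.

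Before the data were examined, the threshold, filters, scaling, inputs and comparisons were fixed, together with alternatives for each: a threshold of 3 or 6, other inputs, another scaling, a pseudocount of 1, no filter on input level, equal depth, a stricter overlap and equal numbers of top regions. The rule for names was fixed as well. Gene names were to be given only with an annotation of the build of the windows, and otherwise the 10 regions of highest enrichment in each library, and up to 10 regions per overlap ranked by the lower of the 2 enrichments, were to be named by coordinate. The gene table at hand is of the assembly GRCm38.p6, whose coordinates differ from mm9, so no gene was placed on a region, no region was called intronic or exonic, and the gene list comparison planned for genes of the germline, the mesoderm and the BMP and WNT pathways was not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.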

Results

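The series asked where SMAD1, T and TCF1 bind the genome while mouse epiblast-like cells turn into primordial germ cell-like cells. SMAD1 carries the BMP signal to chromatin, TCF1 is a transcription factor that responds to WNT signalling through beta-catenin, and T (Brachyury) is a T-box transcription factor of the mesoderm. SMAD1 was profiled at 12, 24 and 36 h in the BV reporter line and at 36 h in the PV reporter line, T in PV and TCF1 in BV, with inputs titled PV, BV and BVSC. Depth was 18180163 reads for SMAD1 at 12 h, 23275288 at 24 h, 14925074 at 36 h in BV and 43354004 at 36 h in PV. The T library held 20736671 reads and the TCF1 library 27360924, and the inputs held 42532115 for PV, 46750433 for BVSC and 134657262 for BV. A typical window held 12.4 counts in the shallowest library, SMAD1 at 36 h in BV. No group had a replicate, so differences below have no replicate check, and the 36 h pair from the 2 lines is the nearest to a repeat.

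T had by far the most called regions in these libraries. The counts come from different antibodies with 1 library each, so they do not rank how widely the factors bind. At an enrichment of 4 or more over input, 642 regions were called for T, against 110 for SMAD1 at 12 h, 47 at 24 h, 15 at 36 h in BV, 70 at 36 h in PV and 40 for TCF1. The filter on all inputs keeps any input below the level of a call, so the background was measured with windows filtered by the other 2 inputs only. Each input against another then gave at most 3 regions in 6 comparisons at full depth. Thinned to the depth of SMAD1 at 36 h in BV, input BVSC against input PV gave 8, of which 5 lay in segments of raised level, beside the 15 regions of that SMAD1 library. Median enrichment was 6.08 for SMAD1 at 12 h, 5.57 at 24 h, 4.54 at 36 h in BV and 5.20 at 36 h in PV, and it was 5.25 for T and 4.94 for TCF1. Regions at 8-fold or more numbered 121 for T, 23 for SMAD1 at 12 h, 10 for SMAD1 at 36 h in PV and 2 for TCF1. The median width was 3 kb in every library except SMAD1 at 36 h in BV, where it was 2 kb. Since windows of 2 kb step by 1 kb, 2 kb is the smallest width possible, and the width of binding below this cannot be resolved. All these counts depended on the threshold, and that of T was 1140 at a threshold of 3 and 234 at a threshold of 6. When every library was thinned to the same depth, 691 regions were called for T, 125 for SMAD1 at 12 h and 22 at 36 h in BV.

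**Figure D1:**
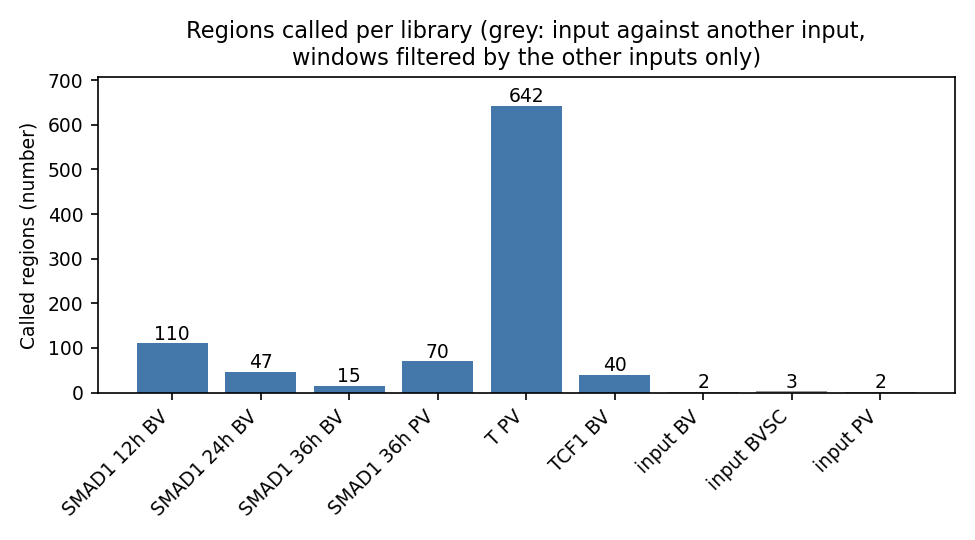
Bars give the number of regions called per library (vertical axis) against the input of the same line, with the highest count of each input at full depth against another input in grey, in windows filtered by the other inputs only. T reached 642 regions, the other immunoprecipitated libraries between 15 and 110, and the inputs at most 3.

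At 12 h in BV, the strongest SMAD1 region lay on chromosome 7 at 52429001 to 52433001, with an enrichment of 21.5 (438 immunoprecipitated and 98 input counts, plain ratio 33.2, 95% interval 26.6 to 41.7). Another region of chromosome 7 at 134753001 to 134757001 reached 20.0, and the next at 30935001 to 30939001 reached 16.3 (446 counts, plain ratio 21.9, 18.2 to 26.5). Chromosome 2 at 104657001 to 104661001 followed with 15.2. Of the 10 strongest regions, chromosome 7 held 4, with the last at 24889001, and chromosome 11 another 4, at 96733001, 121718001, 22871001 and 50712001. SMAD1 regions lay near one another more often than random windows did. At 12 h, 20 of the 110 regions had another within 100 kb, against a mean of 0.94 and a maximum of 6 over 100 random draws. In PV at 36 h this held for 19 of 70 regions, against a random mean of 0.24 and a maximum of 2. Per 10 Mb of usable sequence, SMAD1 at 12 h had 1.37 regions on chromosome 7, 1.17 on chromosome 17 and 1.02 on chromosome 13, against 0.0925 on chromosome 14 and 0 of 110 on chromosome 19.

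The strongest T region lay on chromosome 18 at 13575001 to 13579001, where 723 counts stood against 29 in the input (enrichment 31.9, plain ratio 50.5, 95% interval 34.9 to 76.0). Chromosome 3 at 3348001 to 3351001 followed with an enrichment of 28.8, and chromosome 1 at 184920001 to 184923001 with 27.0. Chromosome 7 at 86932001 to 86936001 and chromosome 10 at 110784001 to 110787001 came next, and the tenth region, on chromosome 2 at 120593001, had 16.7. At the 5 strongest regions the SMAD1 library of the same line measured between 0.984 and 1.53. T regions were spread over 20 chromosomes. They ranged from 1.34 per 10 Mb on chromosome 8 to 3.89 on chromosome 9. Of the 642, 55 had another within 100 kb, above the mean of random draws (31.9) and near but not past their maximum (58). No interval of 1 Mb, counted from the start of each chromosome, held over 4 T regions, a number reached on chromosome 18 between 24013001 and 24990001 and on chromosome 13 between 110412001 and 110607001.

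TCF1 enrichment was weaker. Its strongest region, on chromosome 11 at 108781001 to 108784001, reached 9.12 (162 immunoprecipitated and 38 input counts, plain ratio 21.1, 95% interval 14.8 to 30.9), and the next, on chromosome 11 at 89047001 to 89050001, reached 8.44. Regions on chromosome 9 at 51573001 to 51576001 and on chromosome 1 at 74633001 to 74636001 had enrichments of 7.23 and 6.88. The fifth, on chromosome 3 at 130807001 to 130810001, had 6.78. Of the 40 regions, 7 lay on chromosome 11, 5 on chromosome 8 and 4 on chromosome 19.

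The time course asked how SMAD1 binding moved over 36 h in the BV line, and SMAD1 enrichment fell at nearly all of its regions. Over the 128 regions called at any time, median log2 enrichment was 2.49 at 12 h, 1.78 at 24 h and 1.30 at 36 h. The median difference in log2 enrichment was -0.87 between 24 and 12 h (interval -0.97 to -0.83) and -0.40 between 36 and 24 h (-0.49 to -0.29). Between 36 and 12 h it was -1.23 (-1.29 to -1.12), with 118 of the 128 regions lower at 36 h and 93 lower by over 1. Part of this fall may follow from the choice of regions, since most of them were called at 12 h. At the 70 regions called in PV, a choice that used no BV library, 69 were lower at 36 h than at 12 h in BV and 51 lower by over 1. The strongest 12 h region, on chromosome 7 at 52429001, went from an enrichment of 21.5 to 4.58 at 24 h and 4.89 at 36 h. The region on chromosome 11 at 121718001 went from 14.3 to 7.94 and then 6.27. Called at all 3 times were 13 regions, at 12 h only 79, and at both 12 and 24 h but not 36 h 18. Of the 79, 34 were also called at 36 h in PV. Among the 110 regions called at 12 h, 104 had 2-fold or more at 24 h, 80 at 36 h in BV and 104 at 36 h in PV. A lost call therefore often meant a value below the threshold, not an absence of enrichment. Of the 15 regions called at 36 h, 13 (86.7%, 95% exact interval 59.5 to 98.3) overlapped regions called at 12 h and 13 overlapped regions called at 24 h, against 0 in random relocations, and part of the overlap may come from the shared input. With a different input for the 36 h library, 13 of 16 overlapped in both comparisons, but among equal numbers of top regions only 8 of 15 did at 12 h and 3 of 15 at 24 h, and 1 of 2 in both at a threshold of 6. By the lower of the 2 enrichments, the shared regions of 12 and 36 h were led by chromosome 11 at 121720001, chromosome 11 at 22872001 and chromosome 7 at 30936001, with 6.27, 5.96 and 5.52.

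**Figure D2:**
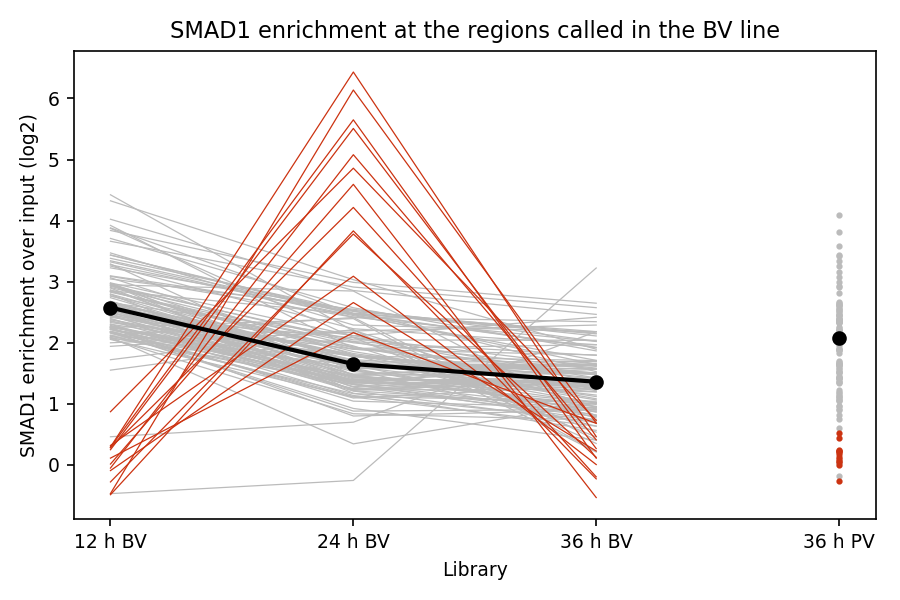
Each grey line follows 1 of 115 regions through the SMAD1 libraries of BV by its log2 enrichment over input (vertical axis), red lines follow 13 regions enriched at 24 h alone, and points on the right give the same regions at 36 h in PV. Black marks are medians of the grey set, 2.58 at 12 h, 1.65 at 24 h, 1.36 at 36 h in BV and 2.07 at 36 h in PV.

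A set of regions went against this course. At 24 h, 13 regions had enrichments between 4.49 and 86.4, whereas the other SMAD1 libraries reached at most 1.83 at them. They were chosen after their values were seen, as regions past the threshold at 24 h and below 1.5 in log2 enrichment in every other immunoprecipitated library. Chromosome 8 held 5 of them between 81862001 and 81898001, led by 81894001 to 81898001 with 2751 counts against 129 in the input (enrichment 86.4, plain ratio 124, 95% interval 104 to 149). Another 4 lay on chromosome 3 between 130813001 and 130905001, 3 on chromosome 11 at 25773001, 52069001 and 52095001, and 1 on chromosome 17 at 35642001 to 35649001, where enrichment was 33.8. All of the 10 strongest regions at 24 h belonged to this set. Without it, 34 regions remained at 24 h, and the median difference between 24 and 12 h was -0.94 over the other 115 regions. The signal was not particular to SMAD1 at every region called at 24 h. Of all 47, T had 2-fold or more at 7 and TCF1 at 8. On chromosome 9 at 123370001, for example, SMAD1 at 24 h measured 4.61, T 3.24 and TCF1 2.62. In BV at 36 h, 2 regions were called at no other time, on chromosome 10 at 82109001 to 82112001 with 9.35 and on chromosome 14 at 71048001 to 71050001 with 4.54. The first of these measured 0.72 at 12 h, 0.84 at 24 h and 0.88 at 36 h in PV.

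SMAD1 binding at 36 h was compared between the lines to see how far it held in both. Of the regions called in BV, 13 of 15 were also called in PV (86.7%, 59.5 to 98.3), with a random maximum of 0, but only 8 of 15 were among the 15 strongest in PV, and at a threshold of 6 the overlap was 1 of 2. Both exceptions were the regions on chromosomes 10 and 14 named above. The shared regions with the highest lower enrichment were chromosome 11 at 121720001 (6.27 in BV and 14.1 in PV), chromosome 7 at 30936001 (5.52 and 17.1) and chromosome 11 at 120092001 (5.34 and 5.65). Enrichment was higher in PV, with a median log2 difference of 0.65 (0.49 to 0.78) over the 128 regions. PV lay below the 12 h library of BV by a median of -0.53 (-0.64 to -0.43). These 2 values depended on how regions were chosen. At the 70 regions called in PV they were 1.05 (0.96 to 1.20) and -0.16 (-0.35 to -0.087), whereas the difference between 36 h and 12 h in BV was -1.18 there. Of the 70 regions in PV, 59 overlapped regions called at 12 h in BV.

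T and SMAD1 regions did not overlap. None of the 70 SMAD1 regions of PV overlapped any of the 642 T regions of that line, which allows a share of up to 4.29% by 3 counts of the total and 5.13% by the exact interval, and random relocation gave a mean of 0.1. Overlap was 0 as well with thresholds of 3 and 6 and with a different input for SMAD1, and 0 of the 110 SMAD1 regions called at 12 h overlapped a T region. At the T regions, SMAD1 in PV had a median log2 enrichment of 0.19 (0.16 to 0.22), above the highest of 10000 random sets (0.04), but only 2 of 642 T regions had 2-fold or more. At the SMAD1 regions, T had a median of 0.22 (0.09 to 0.28) over the shared input and 0.05 (-0.01 to 0.20) over the input titled BVSC. Matched random windows reached at most 0.15 over the shared input, and over the other input the median of T lay at percentile 97.3 of them, below their maximum of 0.16. At the 110 SMAD1 regions called at 12 h in BV, T had medians of 0.23 over input PV and 0.21 over input BVSC, both above the highest random set (0.12 and 0.11).

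TCF1 shared at most 3 of its 40 regions with any other library. Of them, 2 overlapped T regions (5%, 0.611 to 16.9), on chromosome 4 at 107405001 to 107407001, where T measured 12.7 and TCF1 5.39, and on chromosome 8 at 35867001, where no single window had both factors past the threshold (8.28 for T and 1.53 for TCF1). Random relocation gave a mean of 0.04 and a maximum of 1. With SMAD1 at 24 h, 3 of 40 overlapped (7.5%, 1.57 to 20.4, random maximum 1). Of these, chromosome 3 at 130812001 to 130814001 and chromosome 11 at 52096001 to 52099001, chosen after their values were seen, met regions enriched at 24 h alone at their edges, and SMAD1 at 24 h measured 1.24 and 1.19 at the TCF1 summits. With SMAD1 at 36 h in BV, 1 of 15 regions overlapped (6.67%, 0.169 to 31.9), on chromosome 11 at 120092001 to 120094001, with enrichments of 5.34 for SMAD1 and 4.19 for TCF1. That window was enriched in all 4 SMAD1 libraries, 7.89 at 12 h, 4.33 at 24 h and 5.65 at 36 h in PV. At TCF1 regions the median log2 enrichment of T was 0.48 (0.38 to 0.76), above the highest of 10000 random sets (0.22), and that of SMAD1 at 12 h was 0.54 (0.42 to 0.63), also above its highest random set (0.23). Over input BVSC these medians were 0.74 for T and 0.46 for SMAD1 at 12 h, again above the highest random sets (0.26 and 0.28). At a threshold of 6 TCF1 overlapped T at 0 of 7 regions and SMAD1 at 36 h in BV at 0 of 2.

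**Figure D3:**
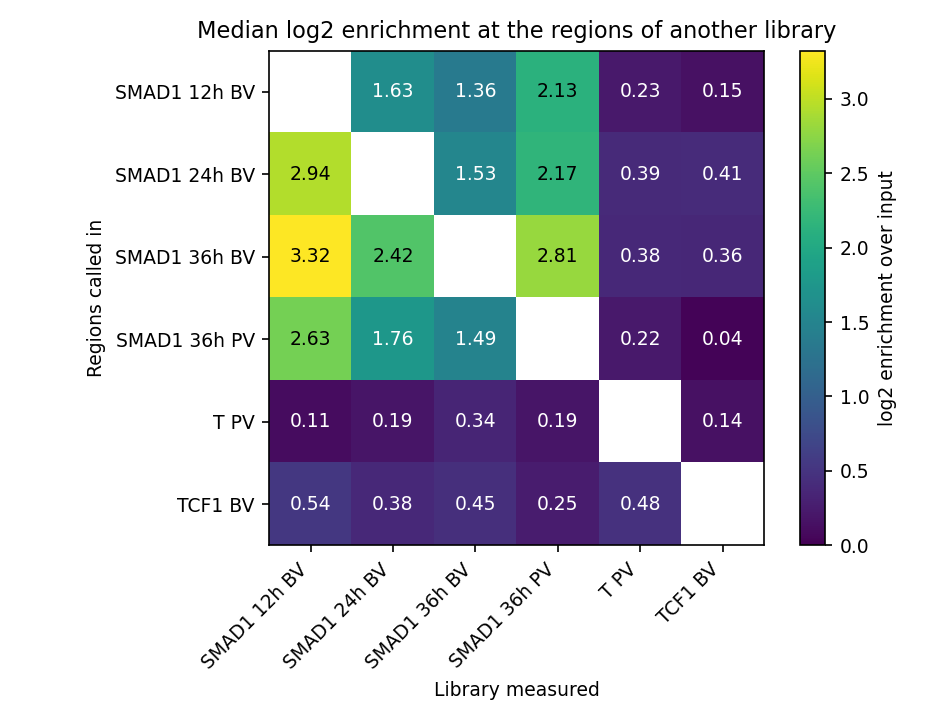
Each cell gives the median log2 enrichment over input (colour and number) of the library on the horizontal axis at the regions called in the library on the vertical axis. The input is that of the same line as the library measured. Among the SMAD1 libraries medians lie between 1.36 and 3.32, and between SMAD1, T and TCF1 none exceeds 0.54. Over input BVSC, not drawn, T at TCF1 regions reached 0.74.

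The libraries differed in the level of parts of their chromosomes, and input BVSC, labelled as the BV line, stood nearer to input PV than to input BV on chromosomes 8, 11 and 14. On chromosome Y it stood with the BV line, at 87.9% of input BV against 0.116% in input PV. Relative to input BV, chromosome 8 stood at 1.17 in input PV and 1.22 in input BVSC, and chromosome 14 at 1.17 and 1.19. On chromosomes 3 and 6 input BVSC stood apart from both other inputs, at 1.20 and 1.18 relative to input BV, against 0.99 in input PV on each. Chromosome 11 was higher in BV libraries than in input PV, at 1.16 in input BV, 1.12, 1.17 and 1.28 in SMAD1 at 12, 24 and 36 h and 1.25 in TCF1, but 0.96 in input BVSC. A segment of 172 kb on chromosome 1 from 12968001 to 13140001 had a median level of 10.2 in input PV, 10.6 in SMAD1 PV and 11.2 in T, against 1.12 in both other inputs. Within it the windows from 13113001 to 13116001 stood at 1.22 in input PV. The raised windows were left out of the calls above for their high input. Among them T met the calling rule at 13026001 to 13029001 (enrichment 6.38, 1035 counts against 314, plain ratio 6.68, 95% interval 5.88 to 7.60) and at 13062001 to 13065001 (4.12, 730 counts against 346, ratio 4.28, 3.76 to 4.87). SMAD1 in the same line measured 0.94 and 1.29 there.

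**Figure D4:**
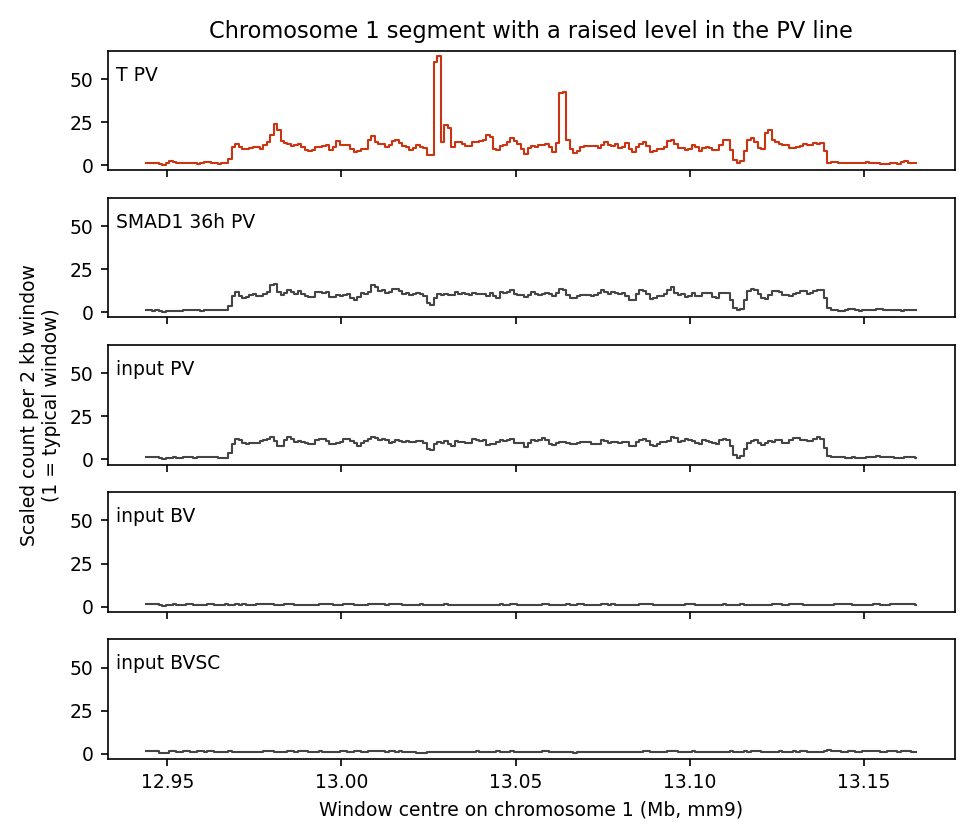
Scaled counts per 2 kb window (vertical axis, 1 is a typical window) are drawn along chromosome 1 (mm9, Mb) for the PV libraries and the inputs of the other cells. The level rises to about 10.2 in input PV between 12968001 and 13140001, and T, in red, stands out at 13026001 and 13062001.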

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

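All weighed tests in this part were chosen after the results were seen, except those on sequencing depth, on a single yield factor and on the correlation of chromosome Y counts, which were set beforehand.

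In the PV line, windows of chromosome Y, which enter no comparison, held more reads in the immunoprecipitated libraries than in the input of that line. Relative to input BV, the level was 1.66% in SMAD1 at 36 h (660 reads, 95% interval 1.54 to 1.80), 0.738% in T (140 reads, 0.621 to 0.871) and 0.116% in input PV (45 reads, 0.0845 to 0.155), against 80.1% or more in BV libraries. Reads of other chromosomes placed on chromosome Y at a single rate in every PV library are argued against by 15.6 reads per 1000000 autosomal reads in SMAD1 against 1.09 in input PV, and the same intervals, with a lower bound of 1.54, argue against a steady share of cells that kept the chromosome. The correlation across windows with input BV was 0.194 in SMAD1 (0.144 to 0.244) and 0.204 in T, in SMAD1 inside the range set beforehand for misplaced reads, but that test was void, since input BV thinned to as many reads as in SMAD1 gave 0.236 to 0.353, short of the bound set for real chromosome Y reads. Both values lay below every such thinning (0.232 or more for T), which share their reads with input BV, and for SMAD1 also below those of SMAD1 at 36 h in BV (0.229 or more) and TCF1 (0.245 or more), for T below those of TCF1 (0.215 or more), but above the lowest of SMAD1 at 24 h (0.152 and 0.153) and at 12 h (0.189 and 0.203), so the BV libraries did not decide it, and DNA with chromosome Y in a share that differed between preparations and misplaced reads at differing rates both may remain, with no other biological explanation tested.

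SMAD1 enrichment was lower at 36 h than at 12 h in BV, and sequencing depth is argued against, since 125 regions at 12 h and 22 at 36 h were called with every library thinned to the same depth. The median log2 difference from 12 h in BV was -0.53 for 36 h in PV and -1.23 for 36 h in BV, but with no library of PV at 12 h this leaves open whether time acted alike in both lines. A single yield factor of 0.32 for all regions left a chi-square per degree of freedom of 3.25 over 70 regions, just past the bound of 3 set beforehand for rejecting it, but with a bootstrap interval of 1.98 to 4.67, added after the value was seen, that holds the bound. Over the regions called in BV without those of 24 h alone (115) it left 20.7, and 2.97 without the 2 regions of 36 h alone on chromosomes 10 and 14, which therefore carried most of that excess. At the 70 regions, the same fit left 4.03 for 24 h in BV and 13.4 for 36 h in PV. A misfit past counting error was therefore not particular to 36 h in BV. A weaker immunoprecipitation at 36 h in BV and a loss of SMAD1 binding with time cannot be told apart with 1 library per time.

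The 13 regions enriched at 24 h alone were tested for DNA that lacks introns, such as cDNA or a plasmid, whose reads would be packed into separate narrow blocks. The median share of excess reads in the highest 1 kb bin was 95.4% (65.6 to 99.5), against a median of 63.3% and a 90th percentile of 94.9% at the other 34 regions of that library. The interval spans that percentile, so neither such DNA nor SMAD1 binding of the usual shape is excluded, and the mm9 exon positions that would decide it were not used here. SMAD1 binding at 24 h stays open as the biological explanation, and low values in the other libraries were a condition of choosing these regions. Regions of TCF1 met 2 of them at their edges, on chromosomes 3 and 11.

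Windows left out for unusual input also held signal above their own input. In T these were the places on chromosome 1 with enrichments of 6.38 and 4.12 in the segment of raised level in PV. In SMAD1 at 12 h they were chromosome 5 at 147071001 (4.36), chromosome 6 at 3150001 (5.55), chromosome 11 at 108872001 (4.36), chromosome 13 at 71158001 (7.57) and chromosome 17 at 39979001 (8.28). At 24 h, 4 places overlapped these, on chromosome 5 (6.35), chromosome 6 (6.60), chromosome 11 (5.93) and chromosome 17 (9.85). The signal was not particular to SMAD1 at all of them, since at the 12 h summits T measured 2.01 on chromosome 5, 3.17 on chromosome 6, 3.02 on chromosome 11 and 2.72 on chromosome 17, and TCF1 2.14, 3.48, 2.44 and 2.74. The values of T depended on the input, and over input BVSC they were 4.16, 4.58, 5.44 and 9.57 in the same order. On chromosome 13 T measured 1.05 over input PV and TCF1 1.24. That place overlaps a region already called at 12 h, at 71159001 to 71161001 (5.87), and its left-out summit held only 17 input counts. On chromosome 17 the scaled input itself was 24.3 at the 12 h summit and 36.3 at the 24 h summit.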

How the results depend on the processing

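Of 108 values of the counts, overlaps and time course under alternatives, 81 stayed near the reported ones (a count within 1.5 times, another value within its interval) and 27 moved. No median difference between SMAD1 libraries changed sign, whereas counts and overlap shares, most of the values, have no sign that could reverse. Leaving out the regions of 24 h alone, and setting T against SMAD1 at 12 h, were alternatives chosen after seeing the data, as was the yield fit without the regions of 36 h alone. Called regions moved mainly with the threshold and the pseudocount. At a threshold of 3 they were 180 for SMAD1 at 12 h, 32 at 36 h in BV, 1140 for T and 74 for TCF1. At 6 they were 58, 19 and 2 for SMAD1 at 12, 24 and 36 h in BV, 19 for SMAD1 in PV, 234 for T and 7 for TCF1. A pseudocount of 1 left 5 regions for SMAD1 at 36 h in BV, 37 in PV, 358 for T and 19 for TCF1. The highest count of an input against another was 0 by the construction of the filter and 33 with no filter. With windows filtered by the other inputs only (chosen after seeing the data) it was 3 at full depth and 8 when thinned. At a threshold of 6 only 2 regions were left at 36 h in BV, and 50% of them overlapped SMAD1 in PV, at 12 h and at 24 h alike, while the overlap of TCF1 with SMAD1 and with T was 0. With equal numbers of top regions, the overlap of SMAD1 at 36 h in BV was 53.3% with PV, 53.3% with 12 h, 20% with 24 h and 0 with TCF1, the 24 h value since all 10 of its strongest regions are those of 24 h alone. At the regions called in PV, the log2 difference of PV was 1.05 from 36 h in BV and -0.16 from 12 h, and the cause was not tested. The other inputs, total scaling and equal depth kept every called count within 1.5 times, with the widest shift from 15 to 22 for SMAD1 at 36 h in BV at equal depth. Among 93 named values, 424 of 465 alternative values lay within counting error and 48 fell below 4-fold. The gene list alternatives were not run, since the gene table is of another build than the windows. No paired analysis was possible because each group holds 1 library. Planted regions of 4-fold were mostly missed at every depth, as the pseudocount lowers their enrichment, and at 5-fold 50% were found in the shallowest library and 35% in the deepest immunoprecipitated one.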

Other observations

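The test in this part was chosen after the result was seen. Chromosome 17 from 86683001 to 86712001 was nearly empty in every BV library, with 4 reads in input BV, 1, 8 and 1 in SMAD1 at 12, 24 and 36 h and 9 in TCF1, whereas PV libraries and the input titled BVSC had reads there (297 in input PV and 321 in input BVSC). The level of input BVSC in this stretch was 0.566 of its 30 kb flanks, against 0.00234 for input BV. The PV libraries stood near the value of input BVSC, at 0.506 for input PV, 0.504 for SMAD1 and 0.468 for T. This stretch was also found from input BV against input PV alone. The label of input BVSC gives it the same reporter genotype as the BV libraries, and its value suggests that it came from cells that lack the gap. Input BVSC also stood apart by a level of 14.2 over 22 kb of chromosome 6 from 122559001 to 122581001 and 3.54 over 157 kb of chromosome 2 from 77708001 to 77865001, where input BV stood at 1.03 and 0.989.

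Small stretches were nearly empty in PV alone. Chromosome 15 from 29055001 to 29061001 held 2 reads in input PV, 2 in SMAD1 and 0 in T, against 202 in input BV and 54 in input BVSC. Chromosome X from 121283001 to 121290001 held 2 reads in input PV, 14 in SMAD1 and 4 in T, against 586 in input BV and 168 in input BVSC.

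The level of chromosome 14 differed between libraries of the PV line, at 1.17 in input PV and in T but 1.07 in SMAD1 at 36 h, relative to input BV. For chromosome 8 these values were 1.17, 1.12 and 1.21.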
